A study of Mus musculus with 6 samples.

How the data were processed

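RNA of heavy complexes from primary mouse astrocytes was sequenced in 6 libraries, 3 from a standard and 3 from an optimized extraction, each labelled batch A, B and C. Per the labels' protocols, equal volumes of lysate were spun through a sucrose cushion, the sequenced mRNA was equalised between pellets (per the series' design text), and libraries were made with a stranded total RNA kit. Per the submitters' processing notes, TopHat2 and featureCounts were used with build mm10; versions, strand setting and annotation are not given in the sources used here. The authors' deposited values are log2 fold changes per gene, optimized over standard extraction, per the file headers. How counts were scaled, how the batches were combined and what made a gene count as listed are not given in the sources used here. Other deposited tables list genes of 1 extraction alone, with a symbol and a biotype and no measured value. A further 6 tables repeat the log2 fold changes for genes of a gene ontology or pathway term; their values differed from the main table by at most 0.

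The planned tests across libraries needed values per library, which were not analysed here, so the plan's fallback for tables of fold changes was used: no test of single genes, and counts of genes at least 2-fold higher or lower. There were no mean expression values either, so random lists could not be matched on expression as planned. Depth is unknown, and no interval that needs it is given. Unmatched columns of per-sample values numbered 0.

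Each gene list, 25 fixed before the data were examined and 6 from the authors' tables, was summarised by its median log2 ratio, which was ranked among the medians of 10000 random lists of the same size drawn from all shared genes. A list was called above or below when its median lay outside the central 95% of the random lists. This describes the deposited values and is no test across samples. The procedure was tested on simulated data, in which the ratios of the 13278 shared genes were permuted and 200 genes were shifted. From these 200 genes 500 lists of 20 genes were drawn. The procedure called 5.6% of lists with no shift and 31.4% with a shift of 0.1 on the log2 scale. With shifts of 0.2 and 0.4 it called 78.6% and 100%. Permuting makes genes independent of one another, which members of a real list may not be. These rates may therefore not hold for the lists reported here. Biotypes and preset lists among genes of 1 extraction alone were compared with the shared genes by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 6 and 50 tests, with a threshold of 0.05.

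Gene identifiers were matched to GENCODE release M21 (GRCm38, the assembly of mm10): 13273 of 13278 shared, 75 of 75 standard-only and 614 of 617 optimized-only genes matched. The symbols of 19 shared and 2 optimized-only genes had turned into numbers in the tables, as spreadsheet dates do, and were taken from the identifier. A representative coding transcript gave coding length, untranslated lengths, GC content and protein sequence. Hydrophobic segments were windows of 19 residues with a mean Kyte-Doolittle value (scale from Biopython 1.88) of at least 1.6 (2 in a stricter alternative), and called N-terminal within the first 40 residues; this is a proxy and not a signal peptide predictor, and mitochondrially encoded proteins were left out. Differences of medians have percentile intervals from 2000 bootstrap draws of genes. Another annotated gene on the same strand overlapped 7.92% of the shared genes, whose counts are uncertain to that extent.

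The genes named by rule were the 12 with the largest log2 ratio in each direction among those at least 2-fold different, up to 4 members of each list with the largest absolute log2 ratio among those at least 2-fold different, and Gfap, Slc1a3, Aqp4, Actb and Eef1a1. The rule as planned also asked for an adjusted p, agreement between batches and a mean value, which the tables lack, and it gave no gene where a list had no member at least 2-fold different. Since nearly all ratios lie above 0, the rule takes the highest members of a list; low members are marked as chosen after their values were seen, and all genes named from the tables of 1 extraction alone, outside the lists, were chosen after the tables were seen. Alternatives were the mean in place of the median, random protein-coding lists matched on 10 bins of coding length (where at least 80% of the members had a coding length), lists without members of the authors' lists, ratios centred on their median, named or protein-coding genes alone, and transcript length. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 20.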

Results

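The series measured RNA bound in heavy complexes (ribosomes, polyribosomes and other RNA-protein particles) of primary astrocytes, the star-shaped support cells of the brain, cultured from newborn C57BL/6JOlaHsd mice of both sexes. Lysates were spun through a sucrose cushion, and RNA-seq was run on the pellets. There were 6 libraries: 3 (batches A, B and C) from a standard extraction, in which scraped and frozen cells were lysed in Triton X-100 with sodium deoxycholate and low salt, and 3 (batches A, B and C) from an optimized extraction, in which cells were lysed on the plate in the mild detergent DDM with more salt. The labels call the batches biological repetitions. The single contrast of the design asks which RNAs each extraction brought into the heavy pellet. The values analysed here are the log2 ratios of optimized over standard extraction in the authors' deposited table, 1 per gene and without an error, so the spread between batches and the depth of each library are unknown and no gene was tested across libraries.

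Nearly all transcripts had a higher value in the optimized extraction, and the genes differed in how far. Of the 13970 genes listed, 13278 were listed in both extractions. Their median log2 ratio in the authors' deposited table was 1.09, a 2.13-fold higher value in the optimized extraction, and 13226 (99.6%) lay above 0 against 52 below. At least 2-fold higher values were listed for 8360 genes (63.0%) and at least 2-fold lower values for 1, Egr1. Per the series' design text the same quantity of mRNA from every pellet was sequenced, and how the authors scaled the libraries to reach this shift is not given in the sources used here, so the shift is not read as a yield, and the accounts that follow set genes against the median of 1.09. After centring on that median, 90 genes lay at least 2-fold above it and 78 at least 2-fold below it, and 89.3% lay within 0.5 of it on the log2 scale. The astrocyte filament gene Gfap was listed at 1.11 and the water channel gene Aqp4 at 0.97 in the authors' deposited table. The glutamate transporter gene Slc1a3 was listed at 0.61, the beta-actin gene Actb at 1.23 and the elongation factor gene Eef1a1 at 1.36 in the same deposited table of the authors.

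**Figure D1:**
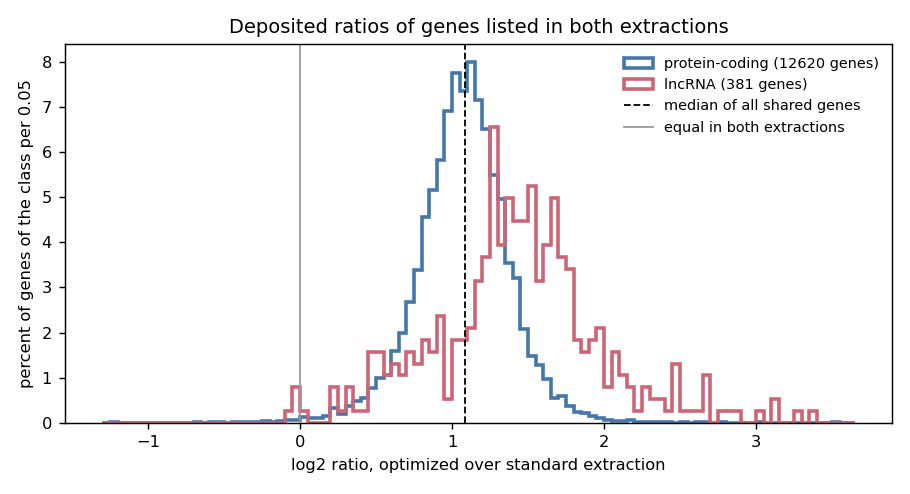
Distribution of the authors' log2 ratios, optimized over standard extraction (x axis), as the percent of genes of each class per bin (y axis), for 12620 protein-coding genes and 381 long noncoding RNA (lncRNA) genes listed in both extractions. The dashed line is the median of all shared genes (1.09), and the lncRNA median lay at 1.43.

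The highest ratios belonged mostly to noncoding and unnamed genes, and the lowest to a mixed set led by an activity-induced transcription factor gene. The authors' deposited table had its highest log2 ratio, 3.52, at Gm14391 (mm10 chromosome 2, 175191065 to 175206917), a predicted protein-coding gene. It was followed in the authors' deposited table by the lncRNA gene 2610037D02Rik (3.37), the unverified transcript genes Gm37795 (3.30) and Gm33366 (3.28), the lncRNA gene Gm21781 (3.28) and the small nucleolar RNA gene Gm23455 (3.21). Meg3, an imprinted lncRNA gene on chromosome 12 (109541001 to 109571726), was listed at 3.14 in the authors' deposited table. The remaining genes of the highest 12 in the authors' deposited table were Gm17275 (3.13), 6720427I07Rik (3.11), Gm26869 (3.08), Gm10801 (3.03) and Gm23130 (3.03). Gm23130 (chromosome 10, 23786470 to 23786543) lies inside the annotated span of Rps12 (23785183 to 23787275) on the same strand, so its reads and those of Rps12 may not have been told apart. Egr1 (chromosome 18, 34859823 to 34864984), an immediate early gene, had the lowest log2 ratio in the authors' deposited table, -1.23. The next lowest named genes, chosen after their values were seen, were Prl2c2 (-0.68), Wipf3 (-0.59), the small nucleolar RNA gene Snord17 (-0.58), the intermediate filament gene Nes (-0.52) and the axonemal dynein gene Dnah5 (-0.44) in the authors' deposited table.

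Long noncoding RNAs lay above mRNAs in the optimized extraction. The 381 lncRNA genes listed in both extractions had a median log2 ratio of 1.43 (quartiles 1.15 and 1.71), against 1.08 for 12620 protein-coding genes, and 295 of them lay above the median of all shared genes. All 9 shared members of a list of nuclear lncRNAs lay above that median, with a list median of 2.00, and 0 of 10000 random lists of 9 genes had a median as high. After Meg3, the authors' deposited table listed Malat1 at 2.84 and Neat1, which builds nuclear paraspeckles, at 2.65. Gm26917, a member of the preset list whose biotype is missing in the authors' deposited table, was listed at 2.34. Xist, which coats the inactive X chromosome, was listed at 2.00 in the authors' deposited table, and was chosen after its value was seen. The 11 host transcripts of small nucleolar RNAs, which are spliced but code for no long protein, had a median of 1.74, with 0 of 10000 random lists as high, and all 11 lay above the median of all shared genes. Among them Snhg17 was listed at 2.35, Gas5 at 2.21, Zfas1 at 2.06 and Snhg15 at 1.97 in the authors' deposited table. The preset list of short structured noncoding RNAs lay on the other side: its 9 shared members had a median of 0.71, 8 lay below the median of all shared genes, and 12 of 10000 random lists were as low. That did not hold for small nucleolar RNA genes as an annotated class, of whose 10 shared members 5 lay above the median of all shared genes and 3 were listed as at least 4-fold higher. Among these 3 was Gm23130, whose reads may not have been told apart from those of Rps12. Within the list, Rnu12, an RNA of the minor spliceosome, was listed at 2.04 in the authors' deposited table, where Rmrp was listed at 1.07 and Rpph1, the RNA of ribonuclease P chosen after its value was seen, at -0.02.

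Far more genes were listed for the optimized extraction alone than for the standard extraction alone, and the optimized-only genes held a larger share of lncRNA and TEC genes than the shared genes. The authors' deposited tables listed 617 genes (4.42%) for the optimized extraction alone and 75 (0.537%) for the standard extraction alone. Of the optimized-only genes 199 (32.3%) were lncRNA genes, against 381 of the 13278 shared genes (2.87%), an odds ratio of 16.1 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 4.3e-129 over 6 tests). TEC genes, an annotation class of unverified transcripts, made up 111 (18.0%) of the optimized-only and 121 (0.911%) of the shared genes, an odds ratio of 23.9 (Fisher's exact test, adjusted p = 1.93e-88). Protein-coding genes made up 95.04% of the shared genes and 260 (42.1%) of the optimized-only genes, an odds ratio of 0.0380 (Fisher's exact test, adjusted p = 1.82e-259). Of the standard-only genes 1 (1.33%) was a lncRNA gene, an odds ratio of 0.457 that did not pass (Fisher's exact test, adjusted p = 0.726), 66 (88%) were protein-coding (odds ratio 0.382, Fisher's exact test, adjusted p = 0.0182) and 3 (4%) were TEC genes (odds ratio 4.53, adjusted p = 0.0390). Among genes the tables mark as named, 27 of 264 optimized-only genes were lncRNA genes against 68 of 12400 shared genes, an odds ratio of 20.7 (Fisher's exact p = 1.18e-23). These tests count genes in the deposited tables, not differences between batches, and the rule by which a gene was listed for 1 extraction is not given in the sources used here. Nearly all shared genes also had higher values in the optimized extraction, and genes could not be matched on expression. How far that shift and low expression account for the excess and its gene classes was therefore not tested.

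Histone genes were more frequent among the optimized-only genes than among the shared genes, and mitochondrially encoded genes were so among the standard-only genes. Of the 617 optimized-only genes 9 (1.46%) were histone genes, against 35 shared genes (0.264%), an odds ratio of 5.60 (Fisher's exact test, adjusted p = 0.00278 over 50 tests). They were Hist1h2bg, Hist1h4a, Hist1h2bk, Hist1h2bp, Hist1h3c, Hist1h3h, Hist1h3i, H1fx and H3f3aos, the last an antisense transcript whose symbol met the list's pattern. The standard-only genes held 1 histone gene, Hist1h4n, a similar share (1.33%, odds ratio 5.11) that did not pass (Fisher's exact p = 0.184, adjusted p = 0.766). Of the 75 standard-only genes 3 were mitochondrially encoded (mt-Co2, mt-Nd3 and mt-Tn), an odds ratio of 42.5 (Fisher's exact test, adjusted p = 0.00278). The test treats genes as independent, whereas these 3 lie on 1 mitochondrial genome with the 13 mitochondrially encoded genes that were shared. Since the listing rule is not given, their listing for the standard extraction alone is not read as absence from the optimized pellets. Other optimized-only genes, chosen after the tables were seen, were the snoRNA host transcripts Snhg8, Snhg11 and Snhg20, the cytokine gene Il6 and the imprinted gene Gnas. The 3 host transcripts gave an odds ratio of 5.89 and did not pass after adjustment (Fisher's exact p = 0.022, adjusted p = 0.366). Standard-only genes chosen in the same way included the synaptic vesicle genes Syp and Syn1, the cytokine gene Il11, the macrophage receptor gene Mrc1 and the collagen-binding integrin gene Itga2.

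**Figure D2:**
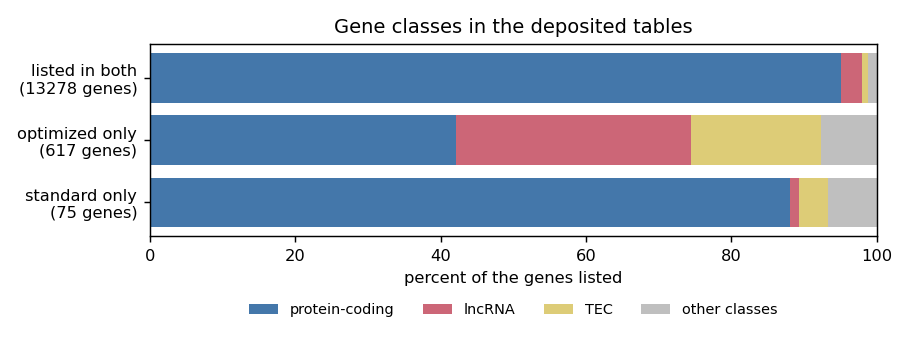
Share of gene classes (x axis, percent of the genes listed) in the authors' deposited tables of genes listed in both extractions (13278), in the optimized extraction alone (617) and in the standard extraction alone (75). LncRNA and TEC genes made up 32.3% and 18.0% of the optimized-only genes.

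Genes of secreted, endoplasmic reticulum (ER) and cell surface proteins lay below the other genes. The study itself chose 6 gene lists, so their direction is not independent evidence. The 280 extracellular matrix genes had a median log2 ratio of 0.77 (quartiles 0.60 and 0.97), and 245 of them lay below the median of all shared genes. The 145 ER lumen genes had a median of 0.80 with 133 below, and the 91 genes of the external side of the plasma membrane a median of 0.79 with 81 below. For each of these lists 0 of 10000 random lists of the same size had a median as low. Individual matrix genes went the other way: the authors' deposited table listed the microfibril genes Fbn1 (chromosome 2, 125300594 to 125507993) at 2.78 and Fbn2 at 1.59, Ltbp2 at 1.93 and Tnc, a matrix glycoprotein gene, at 1.90. The proteoglycan gene Spock1 was the lowest matrix gene in the authors' deposited table, at -0.24, and fibronectin, Fn1, was listed at 0.58, both chosen after their values were seen. Of the ER lumen genes, the authors' deposited table listed the urokinase receptor gene Plaur at 1.48, Arsj at 1.45, the growth factor gene Pdgfb at 1.40 and Pacs2 at 1.39. Of the surface genes, it listed the acetylcholine receptor gene Chrnb2 at 1.37, Gsr at 1.26, Tmem123 at 1.23 and the hyaluronidase gene Hyal2 at 1.22, again as in the authors' deposited table.

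Genes of the ribosome, of alternative splicing and of DNA packaging, also lists of the study's own choice, lay above the other genes. The 81 ribosome genes had a median log2 ratio of 1.48 (quartiles 1.36 and 1.68), 79 of them lay above the median of all shared genes, and 0 of 10000 random lists were as high. The authors' deposited table listed Rps29 (chromosome 12, 69157722 to 69159186) at 2.21, Rps12 at 2.20, Rpl41 at 2.16 and Rpl36 at 1.98. Regulators of alternative splicing (29 genes) had a median of 1.28, with 22 above and 7 of 10000 random lists as high. The RNA-binding protein genes Rbm4 (1.79), Rbm15b (1.74) and Celf4 (1.51) and the splicing factor gene Srsf12 (1.73) led that list in the authors' deposited table. The 46 DNA packaging genes had a median of 1.21, with 33 above and 50 of 10000 random lists as high. The histone genes Hist1h2bf (2.44), Hist1h1d (1.99), Hist1h3f (1.91) and Hist1h4c (1.82) led it in the authors' deposited table. Against random lists matched on coding length the DNA packaging list no longer stood apart (matched random median 1.20).

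The preset lists gave a like division: of 25 lists, 7 lay above the random lists, 11 below and 7 within them. They are not independent of the study's lists, which also held 34 of the 35 histone, 34 of the 35 collagen, 17 of the 20 ER chaperone and 18 of the 40 adhesion genes. The plan that held the preset lists also named the themes of the study's lists, so the likeness is no separate evidence. Besides the nuclear lncRNAs and host transcripts, the lists above were cytosolic ribosomal proteins, histones, translation factors, mitochondrial ribosomal proteins and the nuclear-encoded respiratory chain. The 83 cytosolic ribosomal protein genes had a median of 1.48, with 80 above the median of all shared genes, and 79 of them were also in the study's ribosome list; the 4 others had a median of 1.29, within the random lists. The 27 translation elongation and initiation factor genes had a median of 1.25, with 23 above and 62 of 10000 random lists as high. The authors' deposited table listed Tpt1 at 1.63, Eif4g2 at 1.50, Eef1b2 at 1.47 and Eif4a2 at 1.43. The 35 histone genes (median 1.31, 27 above), the 76 mitochondrial ribosomal protein genes (median 1.21, 54 above) and the 75 respiratory chain genes (median 1.18, 49 above) had 1, 6 and 60 of 10000 random lists as high. Small mitochondrial proteins led the mitochondrial ribosomal protein and respiratory chain lists. The authors' deposited table listed Mrpl33 at 2.15, Mrpl57 at 1.76, Mrpl42 at 1.74, Atp5e at 1.88, Atp5l at 1.80, Cox6c at 1.80 and Cox7a1 at 1.77. The histone, mitochondrial ribosomal protein and respiratory chain lists lay within random lists matched on coding length (matched random medians 1.25, 1.18 and 1.23). The respiratory chain median then lay below the matched one.

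Collagens, adhesion receptors and the folding machinery of the secretory pathway lay below. All 35 collagen genes lay below the median of all shared genes, with a list median of 0.69, and 0 of 10000 random lists were as low. Of the collagens, 32 were also in the study's extracellular matrix list. Collagen genes chosen after their values were seen were Col1a1 (0.65), Col3a1 (0.68), Col6a3 (0.38) and Col14a1 (-0.01) in the authors' deposited table. The 40 adhesion and surface receptor genes had a median of 0.75, 39 lay below the median of all shared genes and 0 of 10000 random lists were as low. Sdc4, a syndecan gene, was listed at 1.19, Itgb5 at 1.09 and Itga3 at 1.05 in the authors' deposited table. The 20 ER chaperone and folding enzyme genes had a median of 0.82, with 19 below and 2 of 10000 random lists as low, and the 3 outside the study's lists had a median of 0.80, within the random lists. The secreted growth factor gene Manf was listed at 1.26 and the proline isomerase gene Ppib at 1.02 in the authors' deposited table, and the chaperone genes Hspa5 and Hsp90b1, chosen after their values were seen, at 0.85 and 0.70. The 28 genes of the secretory translocation machinery had a median of 0.94, with 21 below and 86 of 10000 random lists as low, but by its mean (1.03) the list did not leave the random lists. Within it the authors' deposited table listed the signal recognition particle genes Srp19 at 1.72, Srp9 at 1.62 and Srp14 at 1.38 and the translocon gene Sec61g at 1.64, against 0.75 for the oligosaccharyltransferase gene Stt3a, chosen after its value was seen.

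Marker lists of astrocytes and of most other cell types such cultures can hold also lay below. Whether this follows the cell type or the kind of protein encoded was not tested. The 19 shared astrocyte markers had a median of 0.87, 17 lay below the median of all shared genes and 22 of 10000 random lists were as low. Glutamine synthetase, Glul, was listed at 1.18, S100b at 1.08 and Fgfr3 at 1.02 in the authors' deposited table, and the transporter gene Slc1a2 and the gap junction gene Gja1, chosen after their values were seen, at 0.61 and 0.74. The 30 reactive astrocyte genes had a median of 0.85, with 24 below and 1 of 10000 random lists as low. The authors' deposited table listed the cytokine genes Clcf1 at 1.41 and Ccl2 at 1.23, Psmb8 at 1.24 and S100a10 at 1.17, and the complement gene C3, chosen after its value was seen, at 0.29. Medians were 0.68 for 8 neuron markers (10 of 10000 random lists as low), 0.86 for 8 oligodendrocyte lineage markers (211), 0.70 for 6 endothelial markers (30) and 0.68 for 13 fibroblast and mural cell markers (0). Neuronal Tubb3 and Stmn2 were listed at 1.16 and 1.14, the myelin gene Mbp at 1.27, Olig2 at 1.13, Olig1 at 1.07, and smooth muscle Tagln and Acta2 at 1.22 and 1.12 in the authors' deposited table. Of 16 microglia markers only 3 were shared, with a median of 0.75 that did not leave the random lists (the mean, 0.70, lay below them). Of the 13 fibroblast and mural cell markers, 8 were in the study's own lists, and the 5 left had a median of 0.84, within the random lists; oligodendrocyte lineage markers were also within them by their mean (0.91).

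**Figure D3:**
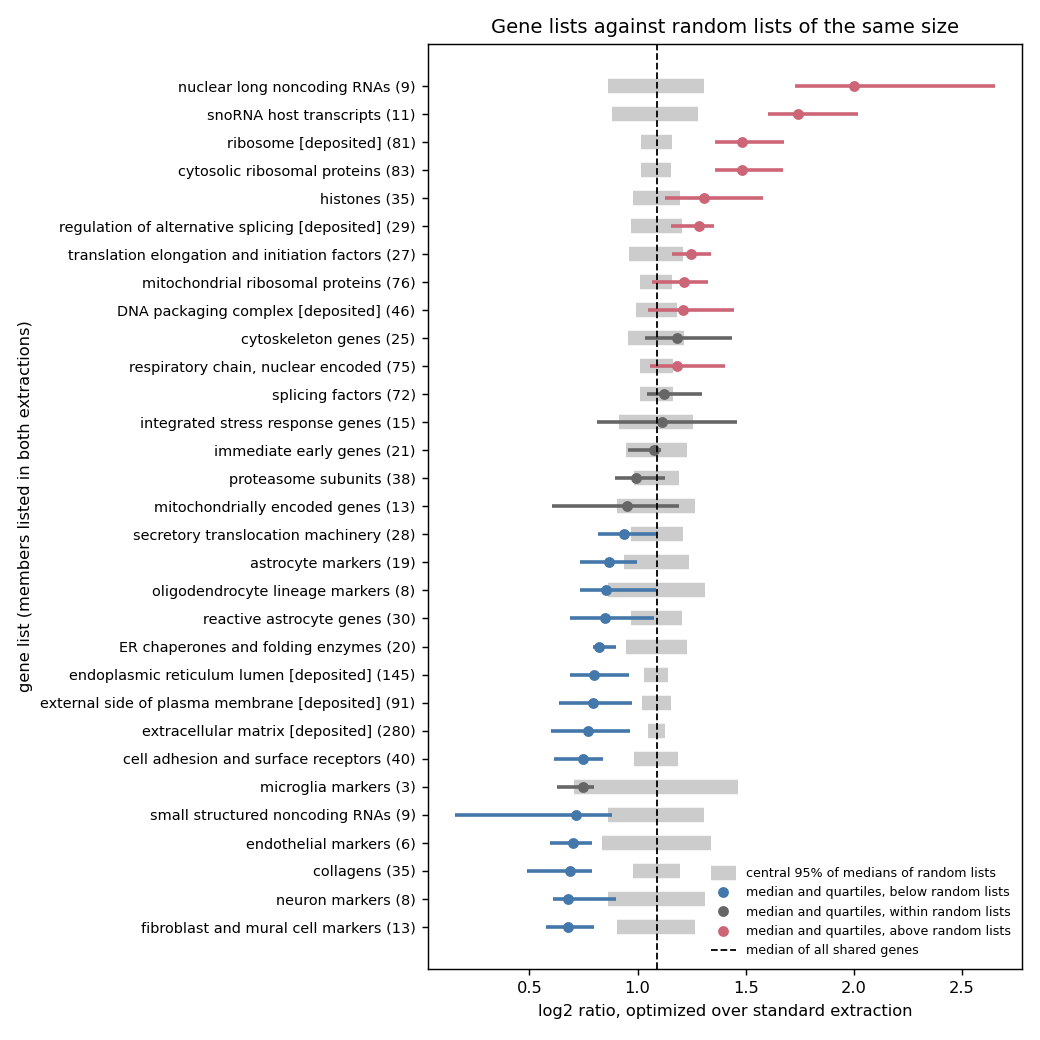
Median (point) and quartiles (line) of the authors' log2 ratios, optimized over standard extraction (x axis), for 25 preset and 6 deposited gene lists (y axis, members in parentheses), beside the central 95% of the medians of 10000 random lists of the same size (grey bars). The lists range from fibroblast and mural cell markers (0.68) to nuclear lncRNAs (2.00), around the median of all shared genes (1.09, dashed line).

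The other lists did not leave the random lists by their medians. The 72 splicing factor genes had a median of 1.12 (the mean, 1.16, lay above the random lists), with Srsf12 listed at 1.73, Snrnp70 at 1.72, Srsf5 at 1.70 and Snrpg at 1.51 in the authors' deposited table. The 25 cytoskeleton genes had a median of 1.18, with the actin-binding genes Tmsb10 at 2.22, Tmsb4x at 2.04 and Pfn1 at 1.47 and the myosin gene Myh9 at 1.92 in the authors' deposited table. The 15 integrated stress response genes had a median of 1.11, and in the authors' deposited table Ppp1r15a was listed at 1.75, Atf4 at 1.74, Nupr1 at 1.69 and Ddit3 at 1.66. The 38 proteasome genes had a median of 0.99, with Psmc3ip at 1.39, a recombination factor whose symbol met the list's pattern, Psmd8 at 1.38, Psma3 at 1.32 and Psmb1 at 1.28 in the authors' deposited table. The 21 immediate early genes had a median of 1.07 but a mean of 0.88, which lay below the random lists. Besides Egr1, the authors' deposited table listed Jund at 1.36, Fosl2 at 1.34, Ier5 at 1.32, Dusp1 at 1.27 and, chosen after their values were seen, Fos at -0.21, Egr2 at 0.40 and Ier2 at 0.48. The 13 mitochondrially encoded genes had a median of 0.95 and a mean of 0.89, the mean lying below the random lists. The ribosomal RNA gene mt-Rnr1 was listed at 1.51, mt-Nd1 at 1.23, mt-Co1 at 1.22 and mt-Cytb at 1.19 in the authors' deposited table.

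Genes with short coding sequences had higher ratios than genes with long ones. Across 12604 protein-coding genes the Spearman correlation of coding length with the log2 ratio was -0.192 (Pearson's r with log2 length -0.215), a relation across genes, which are not independent replicates. Of 10 bins of equal size by coding length, the shortest (111 to 558 bases, 1261 genes) had a median log2 ratio of 1.29 and the longest (3627 to 105639 bases) a median of 1.04. The difference between the shortest bin and all other genes was 0.22 (95% bootstrap interval over genes 0.20 to 0.25), and the medians of the 8 bins of longest coding sequences lay between 1.02 and 1.09. Transcript length gave a weaker correlation (-0.0863), as did the 5' untranslated region (0.000778), the 3' untranslated region (0.0223) and GC content (0.0552). Without the ribosomal, mitochondrial and translation factor lists the correlation with coding length was -0.173 over 12335 genes.

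**Figure D4:**
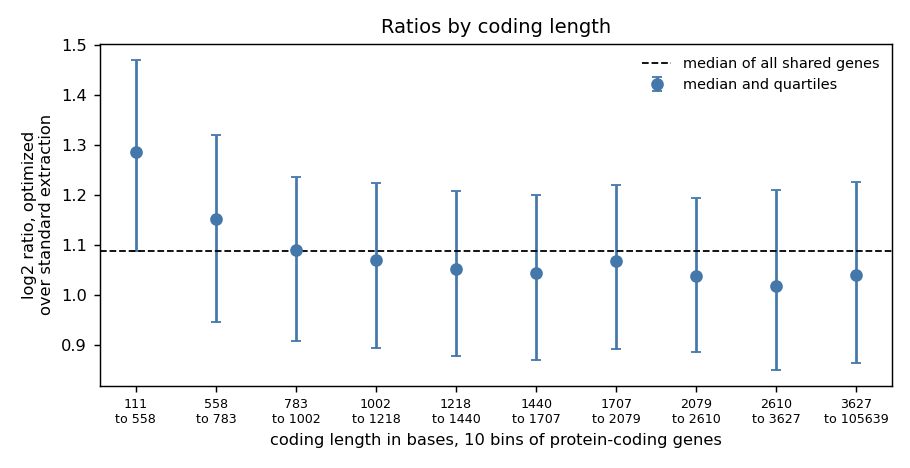
Median and quartiles of the authors' log2 ratios, optimized over standard extraction (y axis), for 10 bins of 12604 protein-coding genes by coding length in bases (x axis). The shortest bin lay at 1.29 and the longest at 1.04.

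Genes of proteins predicted to carry a hydrophobic segment at the start, as signal peptides and signal anchors do, lay below the genes of other proteins. The 1506 genes with such an N-terminal segment had a median log2 ratio of 0.86 (quartiles 0.70 and 1.05), and 79.9% of them lay below the median of all shared genes. The 8174 genes with no segment had a median of 1.14 (quartiles 0.99 and 1.30), a difference of -0.27 (95% bootstrap interval over genes -0.29 to -0.26). The 2822 genes with internal segments alone lay between, at 0.99, with a difference of -0.15 (-0.16 to -0.14). Such N-terminal segments were predicted for 53.6% of the study's extracellular matrix genes, 53.1% of its ER lumen genes and 44.0% of its surface genes, against 1.23% of its ribosome genes and 0 of its DNA packaging genes. Members with no segment were also low in several lists: medians with an N-terminal segment and with none were 0.74 and 0.84 for the matrix genes, 0.79 and 0.79 for the ER lumen genes and 0.74 and 0.89 for the surface genes. For collagens they were 0.67 and 0.69 and for fibroblast and mural cell markers 0.73 and 0.66. None of the 8 neuron markers had an N-terminal segment. Medians with such a segment and with none were 0.87 and 0.99 for astrocyte markers (6 and 7 genes). For reactive astrocyte genes they were 0.83 and 0.81 (12 and 9 genes). Of the 6 endothelial markers 3 had an N-terminal segment and 0 had no segment. Cell type and kind of protein were thus not separated in the marker lists. In other lists members with no segment were not low, with medians of 0.81 and 1.36 for the secretory translocation machinery (10 and 7 genes) and 0.72 and 1.09 for oligodendrocyte lineage markers (4 and 2 genes). The proxy may miss signal peptides, so members with no predicted segment may still be secreted or membrane proteins. The intervals cover the choice of genes and not the spread between batches.

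**Figure D5:**
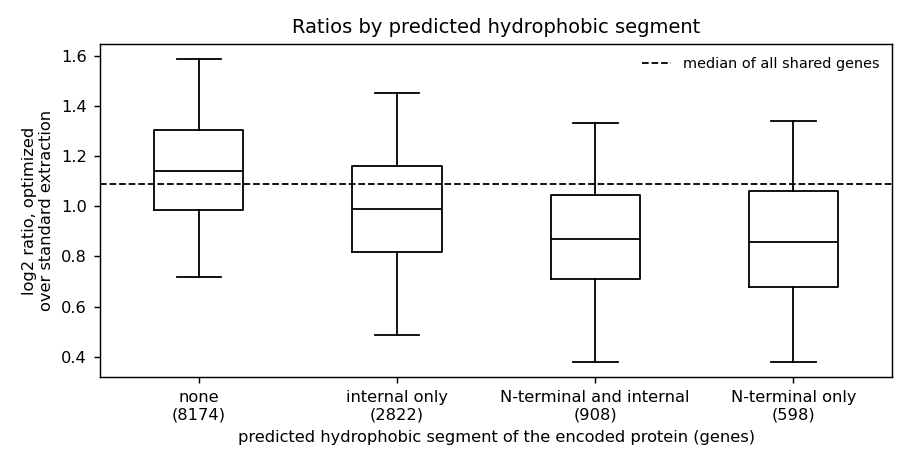
Authors' log2 ratios, optimized over standard extraction (y axis), by predicted hydrophobic segment of the encoded protein (x axis, number of genes in parentheses); boxes are medians and quartiles, whiskers the central 90% of genes. Medians were 1.14 with no segment, 0.99 with internal segments alone and 0.86 for all genes with an N-terminal segment.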

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

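All alternatives were chosen after the data were seen, except centring the ratios. No paired analysis was possible because the deposited tables hold 1 ratio per gene and no values per batch. For the same reason the alternatives set out in advance that leave out a library, use another count model, scaling, pseudocount, filter or adjusted p, run gene set tests on libraries, or match on mean values were not run. Centring on the median of all shared genes gave 90 genes at least 2-fold higher and 78 at least 2-fold lower, against 8360 and 1 as deposited, because a median of 1.09 was taken away. Matched on coding length, the preset lists above the random lists numbered 2 in place of 7: histones, mitochondrial ribosomal proteins and the respiratory chain no longer stood apart, the nuclear lncRNAs and host transcripts have no coding length, and ribosomal proteins and translation factors stayed above. The respiratory chain median of 1.18 then lay below its matched random median of 1.23. Optimized-only genes numbered 264 among named and 260 among protein-coding genes, against 617, while standard-only genes numbered 67 and 66, against 75, so the excess of optimized-only genes was smaller in both. The correlation with transcript length was -0.0863, against -0.192 with coding length; the cause was not tested. By the mean, 25 of the 31 lists kept their side, 4 lists within the random lists left them and 2 lists outside came within them. With length matching 23 of 27 lists kept their side, and without members of the authors' lists 7 did and 3 came within. Depth is unknown, so what it limits cannot be stated.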

Other observations

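The tests of noncoding RNAs and the survey of gene families were chosen after the results were seen; the tests of coding length and of hydrophobic segments were chosen before. Grouping protein-coding genes by the letters of their symbol gave 58 families of at least 20 genes, which were ranked by median log2 ratio. Zinc finger genes named Zfp, most of which encode nuclear proteins, had a median of 1.20 over 341 genes, with 243 above the median of all shared genes. Zbtb genes, also of zinc finger proteins, had a median of 1.27 (39 genes, 28 above), Ube genes of ubiquitin conjugation 1.30 (36 genes, 29 above) and Ankrd genes 1.30 (30 genes, 23 above). The highest families were Rpl (1.46), Rps (1.44), Cox (1.40) and Hist (1.31). Families of nuclear proteins were not all high: nuclear pore genes named Nup had a median of 1.01 (20 genes, 7 above). Transcription factor genes named Gtf had a median of 1.02 (22 genes, 10 above). Solute carrier genes named Slc, which encode membrane transporters, had a median of 0.86 over 227 genes, with 57 above. Tmem genes, named for predicted membrane proteins, had a median of 0.94 (167 genes, 57 above), and Cd surface antigen genes 0.78 (33 genes, 6 above). The Col family, grouped by letters and not the same as the collagen list of 35 genes, was the lowest, at 0.69, with 0 of 36 above.

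Members of the integrated stress response list, which as a whole lay within the random lists, spread widely. The authors' deposited table listed the transcription factor genes Atf4 at 1.74 and Ddit3 at 1.66 and the phosphatase subunit gene Ppp1r15a at 1.75, whose mRNAs carry regulatory upstream reading frames. It also listed Nupr1, another of the list's highest members, at 1.69. It listed the amino acid synthesis genes Asns and Phgdh at 0.81 and 0.81, as in the authors' deposited table; these were chosen after their values were seen, and no difference between kinds of members was tested.

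Long noncoding RNAs had higher ratios than mRNAs (lncRNA median 1.43 against 1.08). Reads from genomic DNA in the optimized pellets, which would raise the unverified TEC genes at least as much, cannot be told apart. Among shared genes the TEC median differed from that of lncRNA genes by -0.33 (95% bootstrap interval -0.42 to -0.15), but 47.2% of all listed TEC genes were optimized-only against 34.3% of lncRNA genes, and with these ranked above all shared genes the TEC median (2.14) exceeded that of lncRNA genes (1.73). Equal release of all nuclear RNA stays open too, since 18 small nuclear and nucleolar RNA genes differed from lncRNA genes by -0.60 with an interval from -1.23 to 0.44. More incompletely spliced RNA in the optimized pellets may contribute. Coding genes with no hydrophobic segment were compared by the share of their exonic sequence outside coding isoforms. Those with a share over 0.5 lay above those with no such sequence by 0.057 (0.031 to 0.089). A difference among coding genes does not show how far such RNA would raise lncRNA genes, so its part in the gap is unknown. No biological explanation was tested because extraction is the only group.

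Short coding sequences had higher ratios, by 0.22 for the shortest of 10 bins. Ribosomal, mitochondrial and translation factor genes were not the whole cause, since the difference without them was 0.21 (0.20 to 0.24). Short transcripts did not account for it either: among transcripts longer than the median the difference was 0.21 (0.16 to 0.26; 173 genes in the shortest bin). Genes with no predicted hydrophobic segment gave 0.21 (0.18 to 0.22), so proteins with a predicted segment do not account for it. Secreted proteins that the proxy misses were not removed, so their part cannot be judged. What underlies the difference stays open, and no biological explanation was tested.

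Genes of proteins with an N-terminal hydrophobic segment had lower ratios, by -0.27. Without members of any preset or deposited list the difference was -0.25 (-0.27 to -0.23), so the lists alone do not account for it. Within 5 bins of coding length it ran from -0.23 to -0.32, and within 5 bins of GC content from -0.25 to -0.29. Members with no segment were also low in the study's matrix, ER lumen and surface lists, though not in the secretory translocation machinery. The segment call is a proxy that may miss signal peptides, so these members cannot show whether another property is at work. Other properties of these genes stay open, and no biological explanation was tested because extraction is the only group.

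Values with no explanation offered follow. Egr1 and Fos, both immediate early genes, were listed at -1.23 and -0.21 in the authors' deposited table, where Jund was listed at 1.36. Of the mitochondrially encoded genes, mt-Co2 and mt-Nd3 were listed for the standard extraction alone, while mt-Co1 and mt-Nd1 were listed at 1.22 and 1.23 and mt-Nd2, chosen after its value was seen, at 0.50 in the authors' deposited table. Gnas, an imprinted gene that codes for a signalling protein, was listed for the optimized extraction alone.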
